A study of Oryza sativa with 12 samples.

How the data were processed

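The data are RNA-seq libraries from 14-day-old seedlings grown under 12 h light and 12 h dark, 3 libraries in each of 4 groups formed by genotype (wild type or pkg) and treatment (none or 10 µM Br-cGMP for 5 h), with groups and replicate numbers taken from the sample titles. Per the submitters' processing notes, CASAVA 1.8 and HISAT2 were used; the genome build, annotation and counting program are not given in the sources used here. The deposited values have no stated unit. They are FPKM by their structure: the value multiplied by the feature length was a whole multiple of 1 step per library within a tolerance of 0.01 for 100% of values above 0, so the authors' values could be turned back into whole reads. The step also showed that the deposited FPKM were already scaled between libraries by median-of-ratios factors. Recovered reads ranged from 6667261 to 9438909 per library.

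Each file listed 112071 features: 37830 reference genes, 20399 added features, 53216 short EPlOSAG features and 626 RNA genes with the prefix ENSRNA. A symbol was given for 2079 of the reference genes, and names come from the files alone; a reference gene table of another assembly was not used here. Of the reference genes, 15025 were listed at 0 in all 12 libraries, among them 5 of 29 listed cytosolic ribosomal protein genes, so a 0 is reported as listed at 0 and not as absence.

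The planned tests assumed counts and named limma as the fallback for other units. As the files hold FPKM, that fallback was used: limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group means of all 12 libraries, trended and robust moderation of the spread, features at 1 FPKM or more in at least 3 libraries (25238) and an adjusted p threshold of 0.05. The pseudocount makes folds of low features too small. Loading and plotting used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Gene lists were tested with camera on the same log values, where voom values had been planned, with a preset correlation of 0.01, and again with an estimated correlation and with fry, for lists of at least 5 tested genes. P-values measure the spread between these libraries.

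The tests, the rule for named genes and the subjects of the 30 gene lists were chosen before the data were examined. The aquaporin list was the exception and was added afterwards. List members had been planned by product descriptions, which the files lack. Members were therefore chosen as symbols after the files were opened and before any test. The exact members, such as the silicon and phosphate transport genes in the root list, were thus not fixed before the files were opened. The list of cyclic nucleotide-gated channels had no symbol and was dropped. Of 963 listed genes, 516 could be tested and 237 were listed at 0. Several lists hold genes whose expression is wider than the list name, such as phosphate transporters among the root markers. The text names the PKG locus, SLR1, GID1 and GAMYB; all genes past the threshold with a symbol, a mean of at least 5 FPKM in the higher group and no overlap between groups; up to 4 members with the smallest p of each list; and at most 2 identifiers without a symbol that rose and 2 that fell in each comparison.

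The procedure was tested on simulated reads with each gene's measured spread and 50 genes changed at each of 4 sizes in wild type Br-cGMP. Changed genes were drawn from those with a mean of at least 5 FPKM, so the shares recovered do not cover lower features. Noise was drawn separately for each gene, so deviations that libraries share across genes were not simulated. For the response in wild type, over 24394 features, it recovered 22% of genes changed by 1 log2 unit, 56% at 2, 80% at 3 and 84% at 5, with 12 false calls among 133 and 1 call when nothing was changed. For the interaction it recovered 10%, 28%, 62% and 76%, with 11 false calls among 99. The measured spread already holds counting noise, which the simulation adds again. With that spread divided by 2, over 24150 features, it recovered 52%, 88%, 86% and 96% for the response, with 11 false calls among 172, and 32%, 72%, 84% and 94% for the interaction, with 11 among 152. The share of false calls was above the nominal threshold in all 4 cases.

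Replicates were compared before averaging. The chi-square per degree of freedom between libraries of a group was 18.39 to 65.88, so none was a repeat of another. Deviations from the group means of same-numbered pkg control and pkg Br-cGMP libraries correlated at 0.31 to 0.36, above 0.1 in all 3 pairs, and each of these 6 libraries correlated best with its own number; the pairing comes from the data alone, as the labels give only the number, and the other comparisons had no such pattern. Alternatives covered the filter, pseudocount, scaling, moderation, groups in the fit, a replicate block, leaving out each library, limma-voom on recovered reads, reference genes alone, and the libraries low in the 4 root genes, the last by leaving out 3 libraries with a mean log2 level of LSI2, NIP2-1, PIP2-3 and OS02G0662000 under 3 or by using that mean as a covariate. Scaling to total reads, limma-voom, reference genes alone, the root alternatives and the block with the 6 pkg libraries alone were chosen after seeing the data. The planned count-based tests were not run; limma-voom was the test run on recovered reads.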

Results

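RNA was sequenced from whole 14-day-old rice seedlings of cultivar ZH11, either wild type or a line labelled as a homozygous mutant of PKG, a cGMP-dependent protein kinase. Seedlings of each genotype were left untreated or were given 10 µM Br-cGMP, an analogue of cyclic GMP, for 5 h. Each of the 4 groups held 3 libraries, which the series describes as biological repetitions. The deposited values were FPKM for 112071 features, and the reads assigned to features, recovered from those values, ranged from 6667261 to 9438909 per library. The series title places the kinase in gibberellin signalling through the transcription factor GAMYB, so the design asks what the nucleotide and the mutation each change, and whether the response to the nucleotide differs between genotypes. All folds below are differences on the log2(FPKM + 1) scale with their standard error, tested with limma on 25238 features and adjusted by the Benjamini-Hochberg method.

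The targeted locus was read first. The files give no symbol for OS02G0281000, the identifier taken for PKG (chromosome 2, 10419062 to 10428014, build not given in the sources used here). Its level was 6.68 ± 0.648 FPKM (SD, n = 3) in wild type control, 8.57 ± 1.19 in pkg control, 5.72 ± 0.973 in wild type Br-cGMP and 7.11 ± 2.98 in pkg Br-cGMP. The mean in libraries labelled pkg was not below that in wild type, with a difference of 0.31 ± 0.29 (adjusted p = 0.951) without Br-cGMP and 0.20 ± 0.29 (adjusted p = 0.87) with it. The labels do not say which part of the gene is altered, so this level does not check the genotype labels, and pkg below means libraries labelled so. SLR1 (OS03G0707600), the DELLA repressor of gibberellin signalling, stood at 446 ± 41.9 FPKM in wild type control, 364 ± 152 in pkg control, 316 ± 35.5 in wild type Br-cGMP and 289 ± 41.9 in pkg Br-cGMP. The gibberellin receptor GID1 (OS05G0407500) lay between 162 ± 24.7 and 198 ± 51.6 FPKM over the 4 groups. GAMYB was low throughout, from 0.338 to 1.98 FPKM in single libraries, and did not reach the level needed for testing.

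**Figure D1:**
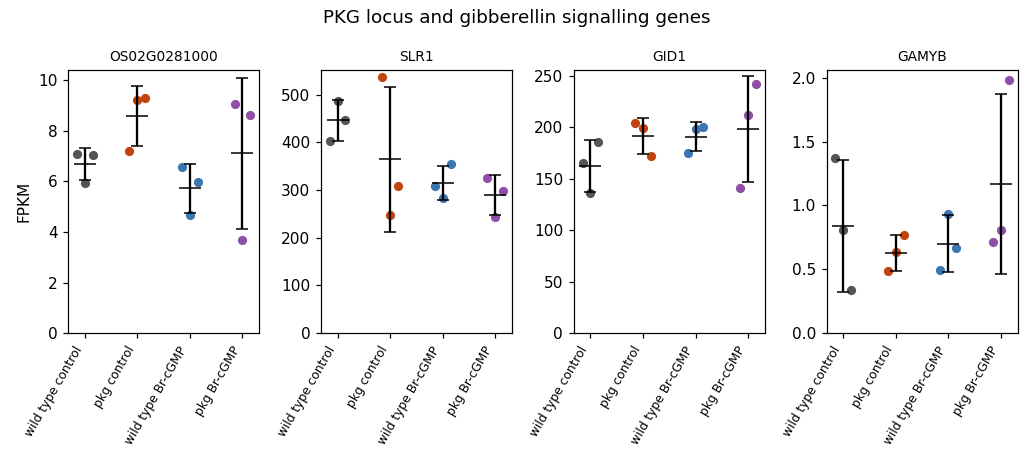
FPKM (vertical axis, from 0) of the PKG locus OS02G0281000, SLR1, GID1 and GAMYB in the 4 groups; each point is 1 library and the black bar is the group mean with its SD (n = 3). The PKG locus is at 8.57 FPKM on average in pkg control and 6.68 in wild type control.

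Several genes known from roots were nearly absent from 3 libraries, which belong to 3 different groups. LSI2, a silicon efflux transporter of roots, was at 0.196 FPKM in wild type control 3, 0.0 in pkg control 3 and 0.181 in pkg Br-cGMP 3, against 41.7 to 452 FPKM in the other 9 libraries. NIP2-1, a silicon channel of roots, was at 15.3, 6.91 and 13.3 FPKM in those 3 libraries and at 117 to 1310 FPKM in the others. The metallothionein gene MT4C showed 5.48, 4.24 and 7.83 FPKM there and 811 to 6220 FPKM elsewhere. LSI2, NIP2-1, MT4C, PIP2-3 and OS02G0662000 were singled out after their values were seen. Of 12 other members of the root marker list, 3, 4 and 1 were under 10% of their median in these libraries. The mean log2 level of 4 root genes, LSI2, NIP2-1, PIP2-3 and OS02G0662000, for which the files give no symbol, was 7.93 ± 0.33 (SD, n = 3) in wild type Br-cGMP, where none of the 3 libraries was low, 5.07 ± 3.31 in wild type control, 5.01 ± 3.7 in pkg control and 5.02 ± 3.86 in pkg Br-cGMP.

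**Figure D2:**
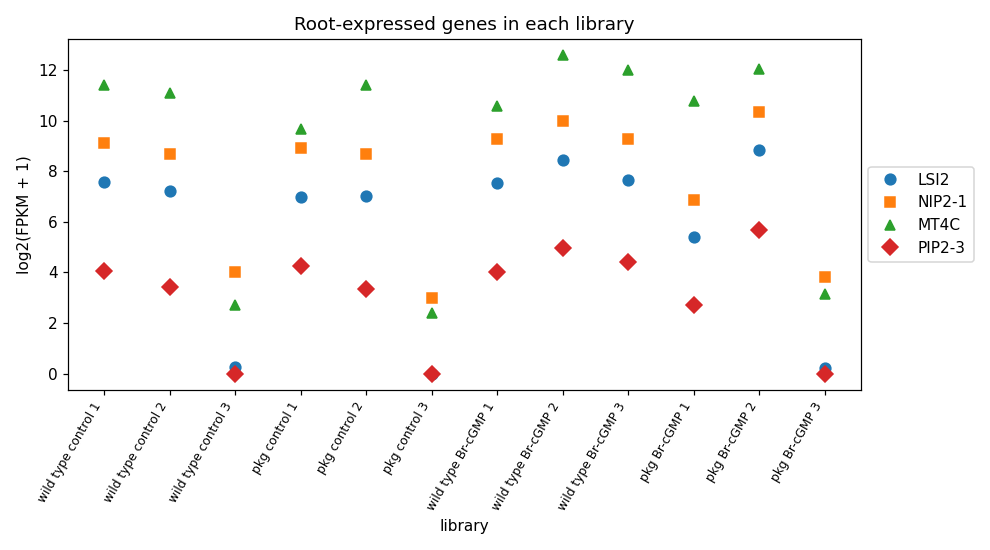
Level of LSI2, NIP2-1, MT4C and PIP2-3 as log2(FPKM + 1) (vertical axis) in each of the 12 libraries (horizontal axis); each symbol is 1 gene. Wild type control 3, pkg control 3 and pkg Br-cGMP 3 lie far below the other libraries.

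In wild type seedlings, no feature passed the adjusted threshold after 5 h of Br-cGMP. The features with an unadjusted p under 0.05 numbered 1346, where 1262 are given by chance, and limma-voom on the recovered reads also called 0. Of the lists displaced upward, jasmonate and pathogenesis-related genes had the smallest p. The jasmonate list had 19 of 24 tested members above control (median 0.89, camera adjusted p = 0.000156, and adjusted p = 0.445 with an estimated correlation), among them the jasmonate-responsive repressor genes TIFY11B (1.95 ± 0.52, from 27.1 ± 10.0 to 119 ± 78.2 FPKM) and TIFY11D (1.5 ± 0.55) and the allene oxide synthase gene CYP74A2 (0.94 ± 0.37). The named genes of this comparison had an adjusted p of at least 0.882. The pathogenesis-related and chitinase list had 16 of 22 members above control (camera adjusted p = 0.000156, and adjusted p = 0.0905 with an estimated correlation), with CHT10 at 1.41 ± 0.48 and CHT8 at 1.53 ± 0.58. The diterpenoid phytoalexin list had 8 of 9 above (camera adjusted p = 0.000571, and adjusted p = 0.445 with an estimated correlation), with the synthase gene KSL4 at 2.11 ± 0.80. The NAC transcription factor list had 5 of 5 above (camera adjusted p = 0.000571, and adjusted p = 0.445 with an estimated correlation), led by NAC67 at 1.29 ± 0.32, from 28.9 ± 9.35 to 71.9 ± 22.4 FPKM. Adjusted over the list alone, 1 NAC gene and 2 of 3 WRKY genes passed. WRKY76 stood at 1.74 ± 0.48 and WRKY24 at 1.95 ± 0.71. The protein phosphatase 2C list had 1 tested gene, so its limma p of 0.0478 is unadjusted and counts as no pass. Here and below, adjustment over a list alone does not cover the number of lists or comparisons, so such passes give little support.

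Further lists were displaced upward in wild type by the same test. Root tissue markers had 14 of 16 members above control (camera adjusted p = 0.000249), and wild type control 3 is one of the libraries low in the 4 root genes. Each of the lists in this paragraph lost its call with an estimated correlation, at an adjusted p = 0.445 for the root and phenylpropanoid lists and adjusted p = 0.459 for the others. Among the root markers the smallest p was that of the phosphate transporter PHT1-1, at 1.11 ± 0.31, from 113 ± 11.7 to 249 ± 67.5 FPKM, followed by PHT1-8 at 0.95 ± 0.37. Phosphate and nitrate supply genes, which include those transporters, gave a camera adjusted p of 0.00364. Expansins and xyloglucan enzymes, which loosen cell walls, had 20 of 26 above (camera adjusted p = 0.00364), with EXPA8 at 2.46 ± 0.69 and EXPA27 at 2.06 ± 0.85. Calcium signalling genes had 43 of 60 above (camera adjusted p = 0.00648; CPK10 0.85 ± 0.27), and phenylpropanoid and lignin genes 20 of 30 (camera adjusted p = 0.0198; HCT2 0.61 ± 0.19 and COMTL2 2.4 ± 1.01). With the mean of the 4 root genes as a covariate, expansins (camera adjusted p = 0.22), calcium signalling (0.0551) and phenylpropanoid genes (0.0551) lost their call, while without the 3 libraries low in these genes they kept it (0.0284, 0.0271 and 0.00153), as did root markers (0.00153). The covariate is made of 4 members of the root list, so it does not test that list.

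Growth-related lists were displaced downward in wild type. Cytosolic ribosomal protein genes were below control in 19 of 23 cases (median -0.36, camera adjusted p = 0.000115), with RPS20 at -0.47 ± 0.21. DNA replication and cell division genes were below control in 37 of 40 cases (median -0.54, camera adjusted p = 0.000571), with the histone gene H2B1 at -0.35 ± 0.14 and RPA2B at -0.63 ± 0.28. With an estimated correlation these lists gave an adjusted p = 0.459 and an adjusted p = 0.679. Of 24 gibberellin genes listed, 7 could be tested and 7 were listed at 0 in all libraries, so most were left untested. The tested members were not displaced (camera adjusted p = 0.843, and 0.843 to 0.997 over the 5 comparisons). They had a median of -0.02 and a mean of 0.14, with the test direction down. Among them SLR1 stood at -0.50 ± 0.26, GID1 at 0.24 ± 0.21 and CYP714D1, which inactivates gibberellins, at 1.55 ± 1.16. Wild type control 3, a library low in the 4 root genes, held CYP714D1 at 3.59 FPKM. Wild type control 1 and 2 held it at 26.2 and 27 FPKM. Without single libraries the difference of CYP714D1 ranged from 0.68 to 1.99.

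In pkg seedlings, Br-cGMP likewise gave no feature past the threshold, and limma-voom called 0. Features at an unadjusted p under 0.05 numbered 685, fewer than the 1262 given by chance, so the lack of calls does not show a lack of response. Leaving out pkg control 1 gave 1 call and leaving out pkg Br-cGMP 1 gave 2. The jasmonate list had 20 of 24 members above control (camera adjusted p = 0.00177), with CYP74A2 at 0.89 ± 0.37 and TIFY11B at 1.08 ± 0.52; named genes of this comparison had an adjusted p of 1. The NAC list had 5 of 5 above (camera adjusted p = 0.000735), with NAC67 at 1.24 ± 0.32, from 31.1 ± 6.67 to 76.4 ± 25.9 FPKM, and 1 gene passed when adjusted over the list alone. Phosphate and nitrate supply had 12 of 14 above (camera adjusted p = 0.000735; PHT1-1 1.16 ± 0.31), root tissue markers 12 of 16 (0.0217), diterpenoid phytoalexins 9 of 9 (0.0227), and calcium signalling 41 of 60 (0.0227). Sodium and potassium transport had 11 of 12 above (camera adjusted p = 0.00419), with the potassium channel gene TPK3 at 0.62 ± 0.28 and the potassium transporter gene HAK5 at 1.02 ± 0.51. With an estimated correlation these lists had an adjusted p from 0.489 (NAC, sodium and potassium) through 0.697 (jasmonate, phosphate and nitrate) to 0.699 (the remaining ones). Without the 3 libraries low in the 4 root genes, jasmonate (camera adjusted p = 0.575), calcium signalling (0.0575) and root markers (0.0575) lost their call, while jasmonate (0.00115) and calcium signalling (0.0192) kept it with the mean of these genes as a covariate. SLR1 stood at -0.27 ± 0.26, GID1 at 0.02 ± 0.21 and CYP714D1 at 0.58 ± 1.16, all of which turned sign without single libraries. The fold changes of the 2 responses, which have separate controls, correlated across features at a Pearson r of 0.212, features not being independent replicates. In wild type and pkg together, 133 features had an unadjusted p under 0.05 in both responses in the same direction and 25 in opposite directions. No count expected by chance was computed for these. Both responses use the same estimate of the spread, so the counts measure no support.

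Without Br-cGMP, 86 features differed between the genotypes, 52 higher and 34 lower in the libraries labelled pkg. Of these, 39 had at most 2 reads in all 6 libraries of one genotype and more in all 6 of the other. The 86 comprised 20 reference genes, 59 features that the files list in addition to the reference genes, and 7 identifiers with the prefix EPlOSAG, and they lay on all 12 chromosomes. OS03G0299700 (chromosome 3, 10518913 to 10520192) was at 81.5 to 115 FPKM in the 6 wild type libraries and at 0.362 FPKM or less in the 6 pkg libraries (adjusted p = 1.86e-07 without Br-cGMP). OS04G0510000 (chromosome 4, 25518258 to 25518789) was at 22.9 to 61.6 FPKM in wild type and listed at 0 in all 6 pkg libraries (adjusted p = 6.4e-06). In the other direction, OS01G0713200 (chromosome 1, 29620958 to 29622314) was at 70.1 to 592 FPKM in the pkg libraries and at 0.107 FPKM or less in wild type (adjusted p = 0.000207). OS06G0685400 (chromosome 6, 28566194 to 28566973) was at 9.2 to 113 FPKM in pkg and listed at 0 in wild type (adjusted p = 0.00821), a call that ended without wild type control 1 (adjusted p = 0.0521) or wild type control 2 (0.0504), by limma-voom (0.0796), with only the compared groups in the fit (0.154) and without the 3 libraries low in the 4 root genes (0.0658). Over all alternatives its adjusted p ranged from 0.000395 to 0.154. The files give no symbols for these 4 genes.

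**Figure D3:**
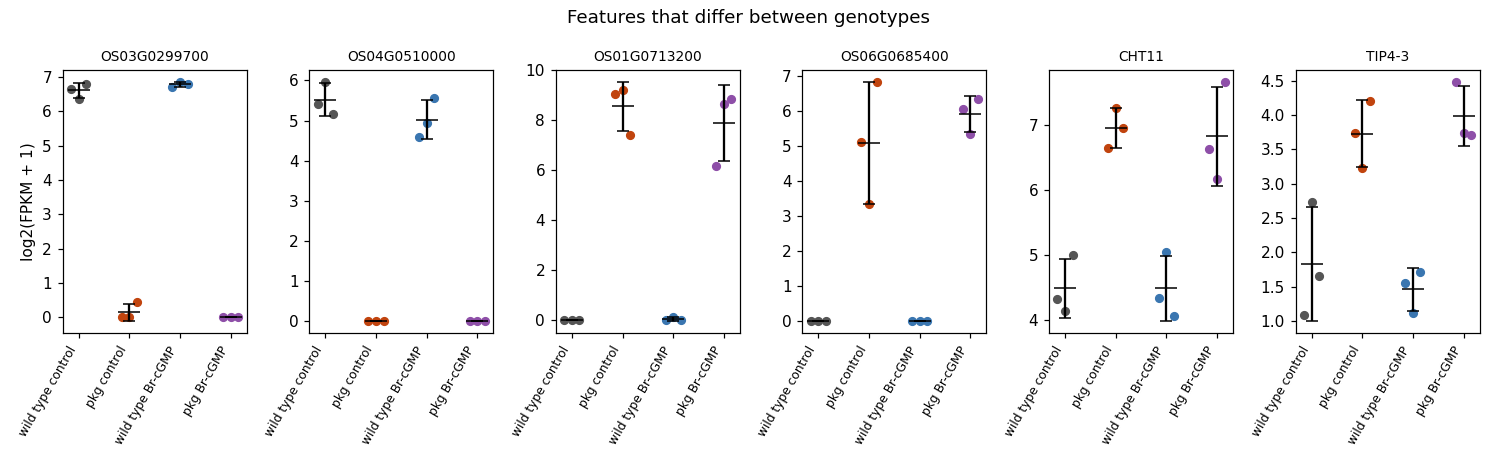
Level as log2(FPKM + 1) (vertical axis) of 4 reference genes without a symbol and of CHT11 and TIP4-3 in the 4 groups; each point is 1 library and the black bar is the group mean with its SD (n = 3). OS03G0299700 and OS04G0510000 are seen in wild type, OS01G0713200 and OS06G0685400 in pkg.

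Among named genes, the chitinase gene CHT11 (OS03G0132900, chromosome 3, 1860429 to 1861772) rose from 22.2 ± 7.64 FPKM in wild type control to 126 ± 27.0 in pkg control (2.47 ± 0.40, adjusted p = 0.0315; 3 of 3 pkg libraries above all wild type libraries). The call of CHT11 ended without wild type control 1 (adjusted p = 0.165), wild type control 2 (0.172), pkg control 1 (0.0678), pkg control 2 (0.174) or pkg control 3 (0.139), in a range from 0.0127 to 0.174 over all alternatives. It also ended with no filter (0.0585), with only the compared groups in the fit (0.053), with reference genes alone (0.0819) and without the 3 libraries low in the 4 root genes (0.079, at a difference of 2.73 ± 0.38). The pathogenesis-related and chitinase list had 16 of 22 members higher in pkg (camera adjusted p = 0.022, and adjusted p = 0.448 with an estimated correlation), with CHT3 at 1.44 ± 0.40 (adjusted p = 0.439) and CHT1 at 1.22 ± 0.40 (adjusted p = 0.646); 1 member passed adjusted over the list alone. All 23 cytosolic ribosomal protein genes tested were lower in pkg (median -0.33, camera adjusted p = 0.000475, and adjusted p = 0.773 with an estimated correlation), for example RPS26 at -0.52 ± 0.33 (adjusted p = 0.947). The same wild type control libraries serve in the wild type response, where this list was lower as well. WRKY76 stood at 1.86 ± 0.48 (adjusted p = 0.343) and passed when adjusted over the list alone, as did 1 aquaporin, TIP4-3 at 1.9 ± 0.43 (adjusted p = 0.198). SLR1 stood at -0.36 ± 0.26 and GID1 at 0.25 ± 0.21. The count of 86 fell to 49 without wild type control 1, 52 without wild type control 2, 56 without pkg control 2 and 55 without pkg control 3. It was 29 without the 3 libraries low in the 4 root genes. With reference genes alone in the fit 12 were called, to be set against the 20 reference genes among the 86.

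Under Br-cGMP, 86 features again differed between the genotypes, 51 higher and 35 lower in pkg, and 67 of them were among the 86 called without Br-cGMP: 40 higher in both, 26 lower in both and 1 in opposite directions. Independent lists of these sizes would share 0.105 higher and 0.0472 lower. The lists are not independent, as both compare the same lines and use the same estimate of the spread, so the sharing measures no support. The 4 genes without symbols were again called, with adjusted p from 1.11e-07 for OS03G0299700 to 0.00319 for OS06G0685400. CHT11 was at 22.4 ± 8.54 FPKM in wild type and 124 ± 69.5 in pkg (2.34 ± 0.40, adjusted p = 0.046), a call that ended without any of the 6 libraries except pkg Br-cGMP 2, with an adjusted p from 0.0526 to 0.23 in those 5 fits. TIP4-3, a tonoplast aquaporin gene (OS01G0232000, chromosome 1, 7297781 to 7298619), rose from 1.8 ± 0.577 to 15.3 ± 5.26 FPKM (2.52 ± 0.43, adjusted p = 0.043). The call of TIP4-3 ended without any single one of the 6 libraries (adjusted p from 0.0646 to 0.201). Both calls also ended with no filter, with only the compared groups or reference genes alone in the fit and with either root alternative, and that of TIP4-3 by limma-voom (0.0946) and with a pseudocount of 0.1 (0.0512). The differences without the 3 libraries low in the 4 root genes and with the covariate were 1.92 ± 0.35 and 2.02 ± 0.36 for CHT11 and 2.65 ± 0.51 and 2.45 ± 0.47 for TIP4-3. Over all alternatives the adjusted p ranged from 0.035 to 0.232 for CHT11 and from 0.0364 to 0.234 for TIP4-3.

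Cell wall lists lay lower in pkg than in wild type under Br-cGMP, where pkg Br-cGMP 3 was the only one of the 6 libraries low in the 4 root genes. The named genes of these lists had an adjusted p from 0.236 to 0.453. Expansins and xyloglucan enzymes were lower in 23 of 26 cases (camera adjusted p = 0.00184, and adjusted p = 0.665 with an estimated correlation), including XTH8 at -1.64 ± 0.40, from 902 ± 164 to 310 ± 144 FPKM, and EXPB4 at -1.62 ± 0.61. Cellulose synthases were lower in 12 of 16 cases (camera adjusted p = 0.00688, and adjusted p = 0.665 with an estimated correlation), with the secondary wall genes CESA4 at -1.71 ± 0.49, CESA7 at -1.86 ± 0.54 and CESA9 at -1.76 ± 0.52; 5 members passed adjusted over the list alone. Auxin response genes were lower in 19 of 25 cases (camera adjusted p = 0.0414, and adjusted p = 0.70 with an estimated correlation), led by IAA21 at -1.55 ± 0.49. In the pathogenesis-related and chitinase list, which was not displaced (camera adjusted p = 0.921), 5 members passed adjusted over the list alone; CHT3 stood at 1.46 ± 0.40 (adjusted p = 0.306), RIXI at -1.75 ± 0.41 (0.213) and GLU2 at -1.4 ± 0.37 (0.293). Adjusted over the list alone, 1 heat shock gene and 1 aquaporin also passed. SLR1 stood at -0.13 ± 0.26 and GID1 at 0.02 ± 0.21. Without pkg Br-cGMP 1 the count of features rose to 200, of which 140 were lower in pkg, and CESA4 (adjusted p = 0.0182), CESA7 (0.0414), CESA9 (0.0233) and GLU2 (0.0197) passed over all features; over all alternatives these 4 genes reached adjusted p values of 0.815, 0.822, 0.843 and 0.811. Without wild type Br-cGMP 3 it was 51 and without pkg Br-cGMP 3 it was 55. Without the 3 libraries low in the 4 root genes it was 35, and the expansin and cellulose synthase lists no longer passed (both camera adjusted p = 0.08), nor did auxin response (0.374); with the covariate they gave 0.0819, 0.053 and 0.417. DNA replication and cell division genes, 30 of 40 higher in pkg (median 0.29, camera adjusted p = 0.261), passed without these libraries (camera adjusted p = 0.00105, and adjusted p = 0.99 with an estimated correlation) and with the mean of the 4 root genes as a covariate (0.00411, and adjusted p = 0.849 with an estimated correlation).

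The test of whether the response to Br-cGMP differed between genotypes called 1 feature, EPlOSAG00000003869, named here because it was the only call. It is 53 bases long (chromosome 3, 12950822 to 12950874) and held at most 3 reads in any library; its interaction was 4.82 ± 0.41 (adjusted p = 0.00606), and limma-voom called 0 (adjusted p = 1 for this feature). Without the 3 libraries low in the 4 root genes its adjusted p was 0.326, and over all alternatives 0.00128 to 1. The count of calls was 3 without pkg control 1 and 2 without pkg Br-cGMP 1. Features at an unadjusted p under 0.05 numbered 523 of 25238, fewer than the 1262 given by chance, so few calls do not show equal responses. By camera, 4 lists differed in response. Expansins and xyloglucan enzymes responded lower in pkg in 21 of 26 cases (camera adjusted p = 0.00705; EXPA8 -2.14 ± 0.98, EXPB5 -1.60 ± 0.79), and pathogenesis-related and chitinase genes in 18 of 22 (0.0123; RIXI -1.90 ± 0.58, CHT10 -1.17 ± 0.68). Cytosolic ribosomal protein genes responded higher in pkg in 19 of 23 cases (0.000797; RPS20 0.58 ± 0.30), and DNA replication and cell division genes in 35 of 40 (0.00118; RPA2B 1.15 ± 0.39). With an estimated correlation the pathogenesis-related list had an adjusted p = 0.469 and the other 3 an adjusted p = 0.908. The expansin list lost its call without the 3 libraries low in the 4 root genes (camera adjusted p = 0.509) and with the mean of the 4 root genes as a covariate (0.244). The genes named here had an adjusted p of 1. SLR1 had an interaction of 0.23 ± 0.37 and GID1 of -0.23 ± 0.30.

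The response to Br-cGMP in wild type and the difference of pkg from wild type without it share the wild type control libraries. Their fold changes correlated across features at a Pearson r of 0.399, and unchanged groups simulated against the same controls gave 0.499. The covariance was 0.1504, against 0.1466 in the simulation, a difference of 0.0038. The 3 control libraries are too few to split. The interaction uses them too, so list calls in these comparisons are not independent of each other. Without wild type control, in the pkg response and between genotypes under Br-cGMP, ribosomal proteins gave camera adjusted p of 0.934 and 0.762. The pathogenesis-related list gave 0.621 and 0.921 there, and DNA replication 0.689 and 0.261, all in the fit of all 12 libraries.

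The remaining lists were not displaced in any of the 5 comparisons. Their camera adjusted p was at least 0.456 for abscisic acid and water deficit, 0.161 for cytokinin two-component, 0.07 for brassinosteroid, 0.696 for peroxidases and glutathione transferases, 0.298 for heat shock and chaperones, 0.0616 for photosynthesis light reactions, 0.359 for iron deficiency, 0.121 for sugar and starch metabolism and 0.167 for aquaporins. Fewer than 5 members could be tested for seed storage (3), ethylene (4), WRKY factors (3), circadian clock (3) and protein phosphatases 2C (1), and none for alpha-amylase and seed hydrolases.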

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

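The splits, the tests of root tissue, depth, locus, lines and genes listed at 0, and the fits without 3 libraries were chosen only after the results were seen; the interaction test and the search for overlapping calls were not.

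A difference between genotypes in the response to Br-cGMP was found for 1 feature and 4 lists. The feature EPlOSAG00000003869 had an interaction of 4.82 on the log2 scale with 2, 2 and 3 reads in wild type control, 0 in all pkg control and wild type Br-cGMP libraries, and 1, 2 and 2 in pkg Br-cGMP. Of 100 splits of the libraries within genotype, 22 gave at least 1 call, and one gave 375, which points to a structure of the samples other than treatment. Of the 80 splits that part all 3 same-numbered pairs of pkg libraries, as the real one does, 6 gave at least 1 call and the highest other gave 3, so chance is not excluded for it in either set. The lists were expansins and xyloglucan remodelling (camera adjusted p = 0.00705), pathogenesis-related and chitinase (0.0123), cytosolic ribosomal proteins (0.000797) and DNA replication and cell division (0.00118), with an adjusted p = 0.469 with an estimated correlation for the pathogenesis-related list and adjusted p = 0.908 for the other 3. Without the 3 libraries low in the 4 root genes the expansin list gave 0.509, the pathogenesis-related list 0.00179, ribosomal proteins 1e-06 and DNA replication 3.87e-06. With an estimated correlation these became adjusted p = 0.918, adjusted p = 0.357 and, for the last 2, adjusted p = 0.851.

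The first pattern weighed is the set of features seen in one genotype only. Of the 86 called without Br-cGMP, 39 had at most 2 reads in all 6 libraries of one genotype and more in all 6 of the other. The tests below were not run on these 39 alone. Overlap and distance to the locus were read over all 86 calls without Br-cGMP, and the covariate over the 86 calls under Br-cGMP. Uneven root tissue between the control groups, as far as the 4 root genes track it, is argued against. Their mean log2 level was 5.07 ± 3.31 (SD, n = 3) in wild type control and 5.01 ± 3.7 in pkg control. A covariate could move nothing in these balanced groups. With that mean as a covariate the median call under Br-cGMP kept 99.1% of its fold. That share cannot decide, since a call had to exceed the spread within pkg Br-cGMP, where these genes varied (SD 3.86). A shift of reads between called features that overlap in position is argued against, as 0 calls overlapped a call in the other direction. That count cannot decide on shared reads left unassigned, moved to a feature that was not called or moved to a called feature elsewhere in the genome. A segment around the PKG locus is argued against as the whole cause, as 3 calls lay within 5 Mb of it, where 2.56% of tested features lie. Loss of PKG and other differences between the lines cannot be told apart, because each genotype is 1 line; the 10 splits of 6 libraries are too few for a share under 0.05, the real split giving 86 calls and the highest other 3 without Br-cGMP and 2 with it (1 of 10 in each).

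The second pattern is the near loss of LSI2, NIP2-1, MT4C and PIP2-3 from wild type control 3, pkg control 3 and pkg Br-cGMP 3. Depth is argued against: at the median level, LSI2 would give 1870 reads in the library with the fewest assigned reads, where 0 were found. A first test of depth read only the level in that library, which is one of the 3, and so could not have decided. Less root tissue may be a candidate explanation, but under the bound set for it the test was undecided: of 12 other root list members, 3, 4 and 1 were under 10% of their median in these libraries, against 0 or 1 in each other library. All 3 carry replicate number 3, as does wild type Br-cGMP 3, which is not low; the labels name no day or batch, so a step shared by number stays open, and no biological explanation was tested, as the groups do not separate these libraries.

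The third pattern is the large number of reference genes listed at 0. Of named genes that overlap an added feature, 48.8% were listed at 0, against 4.7% of those that do not, which is consistent with reads shared by 2 features having been left unassigned. A lack of expression was not tested separately, and no biological explanation was tested.

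For the responses to Br-cGMP the 10 splits are likewise too few. The real split gave 0 calls in wild type and the highest other 1. In pkg the real split gave 0 and the highest other 373, for pkg control 1, pkg control 3 and pkg Br-cGMP 1 against the rest, which points to a structure of the samples other than treatment. That split parts 1 of the 3 same-numbered pairs of pkg libraries; the 3 other splits that part all 3 pairs, as the real one does, gave at most 1 call.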

How the results depend on the processing

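The scaling to total reads, limma-voom, reference genes alone, both root alternatives and the block with pkg libraries alone were chosen after seeing the data; the cause of a change was not tested unless stated. The response in wild type gave 5 calls with no filter, 3 with only its groups in the fit, 2 without robust moderation, 2 with a pseudocount of 0.1 and 0 under every other setting run, including each library left out (0 to 0). The response in pkg gave 0 under every setting except leaving out single libraries (0 to 2). For pkg against wild type without Br-cGMP, 43 were called with only its groups in the fit, 12 with reference genes alone, 29 without the 3 libraries low in the 4 root genes and 49 to 73 without single libraries; under Br-cGMP these were 44, 8, 35 and 51 to 200. Fewer features or libraries enter these fits, and the 86 calls of each main comparison held only 20 reference genes. Other settings gave 80 to 107 and 64 to 96. The interaction gave 2 calls with no filter, 2 with a pseudocount of 0.1, 0 with the stricter filter, 0 by limma-voom, 0 with reference genes alone, 0 without the 3 libraries and 1 to 3 without single libraries. Of 27 list calls by camera, 0 held with an estimated correlation or with fry, which called 0 lists in 1 direction and 2 others in either direction (pathogenesis-related and aquaporins between genotypes under Br-cGMP, adjusted p = 0.0426 each). In the alternative fits, fry in 1 direction called the pathogenesis-related list in the wild type response with a replicate block (adjusted p = 0.0412) and with the root covariate (0.0386), and between genotypes without Br-cGMP with the covariate (0.0193). Without the 3 libraries 23 were called, 20 of the 27 and 3 others; with the root covariate, which does not test the root list it draws on, 21 were called, 19 of the 27 and 2 others. DNA replication between genotypes under Br-cGMP was gained in both, cellulose synthases between genotypes without Br-cGMP (camera adjusted p = 0.0496, and adjusted p = 0.824 with an estimated correlation) and the jasmonate interaction (0.00949, and adjusted p = 0.851 with an estimated correlation) without the 3 libraries, and photosynthesis in pkg (0.0348, and adjusted p = 0.675 with an estimated correlation) with the covariate.

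Of 18 same-numbered pairs of libraries, 7 deviated together with a correlation over 0.1 (from -0.28 to 0.45). They include all 3 of pkg control with pkg Br-cGMP, where all 6 libraries correlated best with their own number, and all 3 among the libraries low in the 4 root genes. With 3 libraries per group such a match can arise by chance, so the pairing is not established. In the other comparisons the libraries share only a number, and of 6 libraries in each, 2 correlated best with their own number. With a replicate block the counts were 0, 0, 81, 80 and 1, and all 27 list calls held. The pkg response also gave 0 calls with its 6 libraries alone and the block. With the block in all 12 libraries the adjusted p of CHT11 was 0.0675 without and 0.0861 with Br-cGMP and that of TIP4-3 0.109, so these calls were lost; it changed no other call named. Most of the 73 named gene results were not calls and lay far from the threshold, so keeping their side says little. All lost calls were those of CHT11, TIP4-3, OS06G0685400 and EPlOSAG00000003869. Of 1294 comparisons, 1234 kept their side of the threshold and direction, 42 lost and 4 gained the call. The sign turned in 14, none of them a call: without single libraries the response in pkg ranged from -0.5 to 0.05 for SLR1, -0.14 to 0.24 for GID1, -0.64 to 1.78 for CYP714D1 and -0.5 to 0.05 for the PKG locus, the genotype difference of GID1 under Br-cGMP from -0.14 to 0.24 and the SLR1 interaction from -0.01 to 0.55. Without the 3 libraries GID1 was -0.22 in pkg and -0.14 between genotypes under Br-cGMP, and -0.01 there with the root covariate. The planned DESeq2 and edgeR alternatives were not run. Depth of 6667261 to 9438909 reads leaves short or low features with a few reads.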

Other observations

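Some further genes varied widely between libraries of the same group, and were chosen after their values were seen. The alpha-amylase gene AMY1.1 was at 466 FPKM in pkg Br-cGMP 1 and at 0.159 FPKM or less in the other 11 libraries, and the glutelin gene GLUA1 was at 8.34 FPKM in the same library against 0.692 to 2.0 elsewhere. SALT, a stress-induced lectin gene, was at 419 to 541 FPKM in wild type control, 502 to 4540 in pkg control, 520 to 1740 in wild type Br-cGMP and 1720 to 2570 in pkg Br-cGMP. NAS1, for nicotianamine synthase, was at 0.392 FPKM in wild type control 3, 0.445 in pkg control 3 and 10.7 in pkg Br-cGMP 3, and at 23.5 to 158 in the others.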
